A study of Mus musculus with 4 samples.

How the data were processed

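Gene expression was measured on 4 single-colour Illumina mouse bead arrays, 2 hybridised with RNA of GFP-positive cells and 2 with RNA of GFP-negative cells. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column with DNase I treatment and converted to biotinylated cRNA with an Ambion MessageAmp kit. The deposited normalized intensities are on a log2-like scale and were made with lumi, an R package for Illumina arrays, per the submitters' processing notes. The version, the background step and the transformation are not given in the sources used here. Sorted values of the 4 deposited columns differed by at most 0.00267, as quantile normalization leaves them, and every array had a median of 8.09 (range 7.71 to 16.07). The values were treated as log2 without a further transformation. What the transformation does at the dim end is unknown, and a value near 8 has no known linear equivalent.

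A deposited table of unnormalized intensities was also at hand. Its 4 signal columns carry names that match no sample label, so they were not assigned to samples and were not used. The deposited detection p-values in that table give, per the file headers, each probe's detection on an array. They were used without assigning columns to samples, only to count the arrays on which a probe had a detection p under 0.05. Of 45992 probes, 15787 were detected on at least 2 arrays, 12788 on all 4 and 27317 on none. The central 95% of the values of probes detected on no array lay between 7.88 and 8.16, a narrow band, so that log2 changes of dim probes are likely understated. At the other end the scale stops near 16, and whether the brightest probes can still show a rise is unknown. The number of arrays limits the precision of each value.

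The design fixed before the data were examined assumed normalization of the unnormalized signals with neqc. Those columns could not be assigned by their names, and an assignment by comparing their values with the labelled columns was not made. The deposited normalized values took their place, and the rest of the design was kept. Probes detected on at least 2 arrays were tested. Probe names that begin with scl and 1 or 2 zeros continue with a number that was read as an NCBI Gene ID. Of 11868 such numbers, 82.6% were in the gene table used for names (assembly GRCm38), against 18.5% expected for random numbers of the same size. This gave symbols to 9807 probes of 8109 genes. Across the 511 genes with a second detected probe, the log2 changes of both probes had a correlation of 0.75 (across genes, which are not independent replicates). Names that begin with scl and no zero matched at 10.6% against 13.4% by chance, and these and all other names were left as probes without a symbol. No coordinates are given, because the build behind the array is not given in the sources used here. Each gene was represented by its probe with the highest mean, and a probe without a symbol was tested as its own feature. In all, 15215 features were tested, 3983 of them genes with a symbol and 220 of them immunoglobulin or T-cell receptor probes that the files name.

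Groups came from the sample labels. GFP-positive minus GFP-negative was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend and without a block, with 2 residual and 3.40 prior degrees of freedom. P-values were adjusted over all 15215 features by Benjamini and Hochberg, and a feature was called at an adjusted p under 0.05. Every adjusted p of a gene is from this two-sided limma test. An exact permutation of 2 against 2 arrays cannot go below 0.33, so no other splits of the arrays were counted. The 26 gene lists were fixed beforehand. Only members with a matched and detected probe could be tested, for example 15 of 62 for secretion and 15 of 38 for B-cell identity. Some genes are in several lists. Lists with at least 3 tested members were compared with the other features by camera with a preset correlation of 0.01, adjusted over the 20 lists tested. An estimated correlation and fry were alternatives. The estimated correlation rests on the 2 residual degrees of freedom of 4 arrays. Members were also counted with p-values adjusted over the list alone. Genes were named by a rule fixed beforehand. It took the 8 largest increases and the 8 largest decreases among called genes with a symbol whose groups did not overlap, leaving out symbols of clones and gene models. It added every measured BCL-2 family member, up to 4 called members of each other list with the largest change (or the member with the smallest p where none was called), and a short set of B-cell regulators, of which Xbp1, Bach2 and Tnfrsf13b were measured. This rule named 62 genes, 47 of them called, and 2 of the 62 are not reported here by name. A probe or gene named outside it is said to have been chosen after its values were seen.

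In a test on simulated data for this comparison of 2 against 2 arrays, 50 of 15215 features were changed at each size. The same functions recovered 10% of changes of 0.5 log2 units, 88% of changes of 1, and 100% of changes of 2 and of 3. There were 10 false calls. The simulated noise was independent between arrays, with variances drawn from the fitted prior. Neither a shared replicate effect nor the narrow dim end was simulated. Far fewer features were changed than the 1692 called on the real arrays, and the adjusted p depends on the share of changed features. These rates may therefore not hold for the real arrays. Alternatives changed the filter on dim probes, the choice of probe, the variance prior, the block, the threshold, the set test and the array left out. Cyclic loess, centring on the tested features, a filter on mean intensity and the exclusion of receptor segment probes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes without a matched probe, among them Prdm1, Tnfrsf17, Mcl1, Irf4 and Pax5, were not analysed here.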

Results

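Transcript levels were measured in cultured mouse B cells of C57BL/6 background that lack Prdm1, the gene of the transcription factor Blimp-1, which drives plasma cell differentiation. The cells were grown with CD40 ligand, IL-4 (10 U/mL) and IL-5 (10 U/mL), signals that stand in for T-cell help, and were separated by flow cytometry on day 4 by their GFP fluorescence. The labels call the GFP-positive cells pre-plasmablasts and the GFP-negative cells blasts. Each group had 2 arrays. The comparison addressed how cells arrested on the way to plasmablasts differ from activated blasts of the same genotype, and the study was concerned with regulators of cell survival. The labels do not say whether the replicates came from separate cultures or mice. P-values of single genes therefore measure only the spread between these arrays, which may be technical. Camera p-values of lists rest instead on the spread across genes, with a low preset correlation between them. They may be far too small where members of a list vary together more than that. They do not measure how a list varies between cultures or mice. Prdm1 itself was not analysed here, and the genotype label was therefore not checked on its transcript.

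Array probes for the reporter followed the sort. The eGFP probe read 12.73 ± 0.02 log2 units in GFP-positive cells and 9.34 ± 0.08 in GFP-negative cells (mean ± SD, n = 2 each), a rise of 3.40 (SE 0.08, adjusted p = 3.07e-04). Probes for an internal ribosome entry site (IRES) and for the neomycin resistance gene (NeoR) rose by 1.57 (SE 0.08, adjusted p = 0.00113) and 2.18 (SE 0.15, adjusted p = 0.00188). Probes named GFP, AmpR, Cre and Luciferase were detected on 0 of the 4 arrays. These probes were picked from the names in the files after their values were seen. The labels do not say which locus carries GFP.

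Among genes with a symbol, 211 rose and 231 fell in GFP-positive cells. Ighg3 and Ighg1, the constant regions of the switched isotypes IgG3 and IgG1, had the largest increases among genes with a symbol. Their changes were +3.88 log2 units (SE 0.11, adjusted p = 4.60e-04) and +2.37 (SE 0.10, adjusted p = 9.40e-04). Whether their probes tell the gamma constant regions apart was not tested. Crip1, a LIM-domain protein, rose by 2.23 (SE 0.08, adjusted p = 6.15e-04), and Cdkn1a, the cyclin-dependent kinase inhibitor p21, by 1.94 (SE 0.09, adjusted p = 9.91e-04). A kappa variable segment gene of the Igkv1 family (+1.93), Sspn (+1.73) and Serf1 (+1.63) were also among the 8 largest increases. Cd72, an inhibitory co-receptor of the B-cell receptor, had the largest decrease at -3.96 (SE 0.14, adjusted p = 6.15e-04). It was followed by Il4i1, an amino acid oxidase induced by IL-4, at -2.99 (SE 0.21, adjusted p = 0.00188) and by Fcer2a, the low-affinity IgE receptor CD23, at -2.36 (SE 0.27, adjusted p = 0.00741). The chromatin organiser Satb1 (-2.20), Sorl1 (-2.11), Crhbp (-2.04), the antiproliferative gene Btg1 (-1.73) and Bach2 (-1.71), a repressor of plasma cell differentiation, completed the 8 largest decreases. The naming rule admitted only genes without an overlap between the groups, so this trait adds no support. Across all tested features, 8495 of 15215 had no overlap. Leaving out 1 array could not turn the direction of a gene without an overlap, so the kept directions add no support either.

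**Figure D1:**
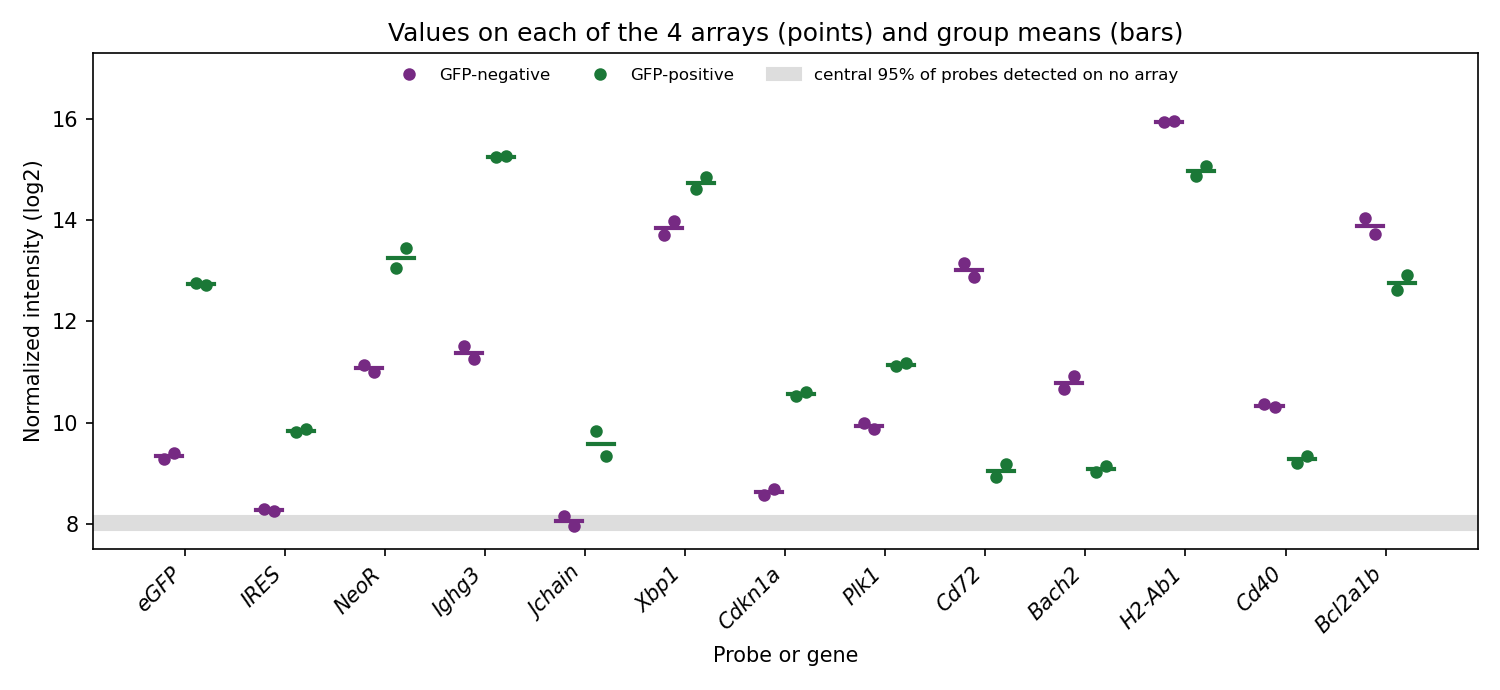
Normalized intensity (log2, vertical axis) of 3 reporter probes and 10 genes on each array, with GFP-negative cells in purple and GFP-positive cells in green. Points are arrays, bars are group means, and the grey band holds the central 95% of values of probes detected on no array. Ighg3 lay at 15.24 and 15.27 in GFP-positive cells and at 11.51 and 11.25 in GFP-negative cells.

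In all, 887 of 15215 features were higher and 805 lower in GFP-positive cells (limma, adjusted p under 0.05). Of these, 299 were higher and 131 lower by at least 2-fold. Of the immunoglobulin and T-cell receptor probes, 147 were at least 2-fold higher. All other features gave 152 higher and 130 lower by at least 2-fold, and 708 higher and 804 lower among all calls. After cyclic loess these other features gave 801 higher and 626 lower, so the direction in which they lean depends on the normalization. Genes with a symbol made up 211 of the higher and 231 of the lower features. Among the 20 features with the largest change, 15 have no symbol, so much of the difference lies in transcripts that are not named here. Probes scl0002383.1_139-S (+4.08) and scl0002365.1_226-S (+4.01) rose most, and scl0002355.1_29-S (-3.58) and scl0002394.1_36-S (-3.29) fell most among unnamed probes, all chosen after their values were seen. With the replicate number as a block, 1861 features were higher and 2125 lower, but the labels do not state such a pairing. Without the block, the counts rest on few arrays. They were 554 higher and 336 lower without GFP-positive replicate 1, 555 and 365 without GFP-positive replicate 2, and 492 and 352 without GFP-negative replicate 2. Of 20 lists tested, camera called 7 in the upward and 3 in the downward direction. None of these 10 calls held when camera used an estimated correlation (adjusted p = 0.304 to 0.355). That version rests on the 2 residual degrees of freedom of 4 arrays. The estimated correlation was negative for some of these lists, such as G2 and mitosis (-0.02). For others it was above the preset 0.01, such as pro-survival BCL-2 (0.20) and DNA replication (0.14). For lists with a negative estimate, the loss therefore does not show that correlation between genes accounts for the calls. For lists with a positive estimate this stays undecided.

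Of 104 heavy-chain variable segment probes tested, 83 were higher and 0 lower, with a median change of +1.46. Of 102 kappa variable segment probes, 89 were higher and 0 lower (median +1.31), and all 3 lambda variable segment probes were higher (median +1.24). These classes, read from the probe names after the data were seen, were called by camera (adjusted p = 1.66e-50, 4.19e-57 and 1.14e-04), and not with estimated correlations (adjusted p = 0.172, 0.141 and 0.141). Segment probes of related sequence can bind each other's transcripts, so their number does not count separate genes. For the same reason the camera p-values of these classes, which rest on a low preset correlation between probes, may be far too small. They do not measure how firmly a class moved. Only 2 of 52 T-cell receptor segment probes were detected, and neither was called. Among 9 constant region probes, 4 were higher and 1 lower. The probe named IGHG1 rose by 3.04 (SE 0.23, adjusted p = 0.00245), and the lower one, IGHD of surface IgD, fell by 1.64 (SE 0.11, adjusted p = 0.00188). The other 3 higher ones, of the lambda constant regions IGLC1 (+0.66), IGLC2 (+0.49) and IGLC3 (+0.50), were not stable. IGLC1 lost its call without GFP-positive replicate 1 (adjusted p = 0.115) or 2 (adjusted p = 0.0993) or GFP-negative replicate 2 (adjusted p = 0.0794), IGLC2 whichever array was left out (adjusted p from 0.0631 to 0.0794), and IGLC3 without GFP-negative replicate 1 (adjusted p = 0.109) or 2 (adjusted p = 0.134) or GFP-positive replicate 2 (adjusted p = 0.115). In the fixed list of immunoglobulin loci, 3 of 6 tested genes rose, 0 fell and 3 were not called (3 also when adjusted over the list alone; camera adjusted p = 6.51e-04; adjusted p = 0.304 with an estimated correlation). The 3 that were not called, Ighm (+0.05, adjusted p = 0.731), Igkc (+0.04, adjusted p = 0.806) and Iglv1 (+0.06, adjusted p = 0.763), had means from 15.83 to 16.02, at the top of the scale. A dimmer Iglv1 probe had a change of +1.48.

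**Figure D2:**
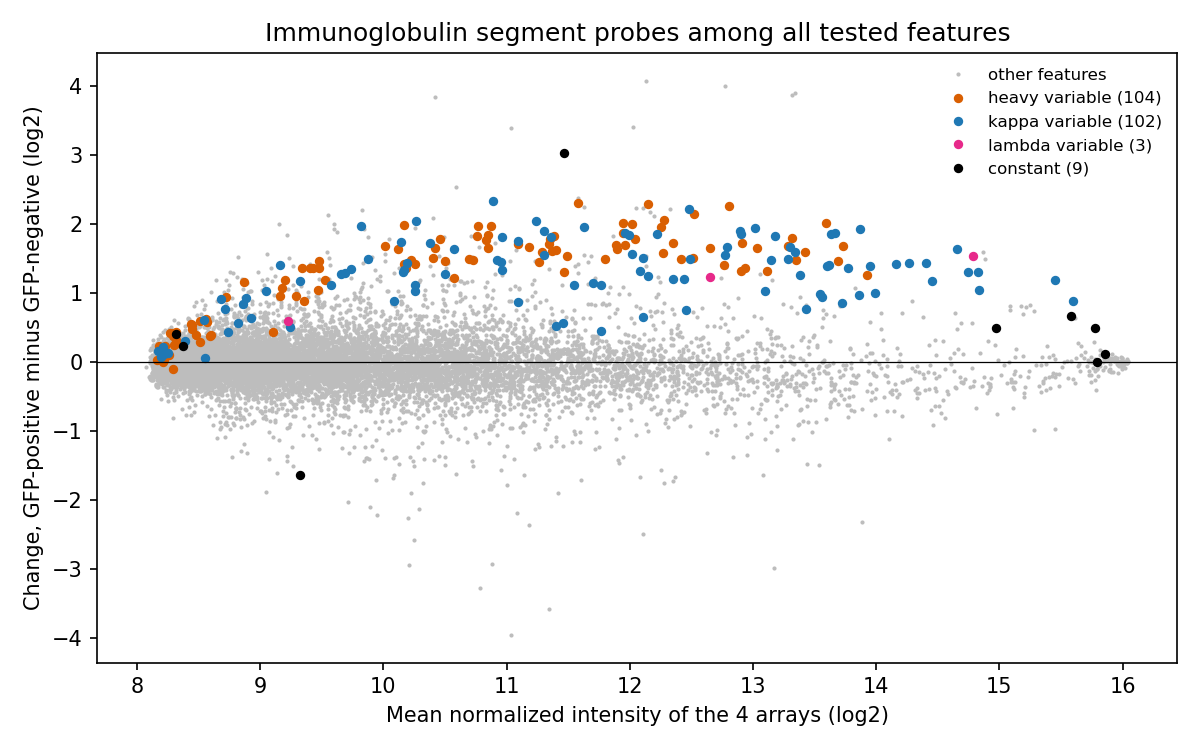
Change between the groups (log2, GFP-positive minus GFP-negative) against mean normalized intensity of the 4 arrays (log2) for every tested feature. Coloured points are immunoglobulin probes by segment class. Of the heavy variable probes 103 of 104 lie above 0, and the 106 brightest features hardly moved, with 5 called.

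Of the 30 genes in the list for the antibody-secreting cell program, only 5 were tested. Of these, 3 rose, 0 fell and 2 were not called (3 higher when adjusted over the list alone). Jchain is also in the list of immunoglobulin loci, and Xbp1 in that of secretion. Xbp1, the transcription factor that builds the secretory apparatus, rose by 0.88 (SE 0.13, adjusted p = 0.0161) and Ell2, an elongation factor for secretory immunoglobulin mRNA, by 0.70 (SE 0.15, adjusted p = 0.0443). Jchain, which joins IgM and IgA polymers, had a change of +1.53 (SE 0.18, adjusted p = 0.00795). It was detected on 2 of the 4 arrays. Setting each GFP-negative array no lower than the dimmest probe detected on all 4 arrays leaves a change of +1.40 on this scale. The dim end has no known linear equivalent, so no fold is given. The list was called by camera (adjusted p = 0.00344; adjusted p = 0.313 with an estimated correlation). The call of Xbp1 was lost without GFP-positive replicate 2 (adjusted p = 0.0601), and that of Ell2 without GFP-positive replicate 1 (adjusted p = 0.0811), GFP-negative replicate 1 (adjusted p = 0.0795) or GFP-negative replicate 2 (adjusted p = 0.135).

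Among genes of the endoplasmic reticulum and protein secretion, 9 of 15 tested members rose, 0 fell and 6 were not called. Adjusted over the list alone, 11 were higher and 1 lower. Spcs2, a subunit of the signal peptidase, rose by 1.05 (SE 0.17, adjusted p = 0.0192), the translocon subunit Sec61b by 0.98 (SE 0.15, adjusted p = 0.0154) and Ssr4, of the translocon-associated complex, by 0.81 (SE 0.11, adjusted p = 0.0122). Camera called the list (adjusted p = 1.37e-06; adjusted p = 0.304 with an estimated correlation). Spcs2 lost its call without GFP-negative replicate 2 (adjusted p = 0.0592) and Ssr4 without GFP-positive replicate 2 (adjusted p = 0.0537). In the list of amino acid transport and ATF4 targets, 3 of 5 members rose and 2 were not called (3 when adjusted over the list alone; camera adjusted p = 0.00574; adjusted p = 0.321 with an estimated correlation). They were the threonyl-tRNA synthetase Tars (+0.54), the seryl-tRNA synthetase Sars (+0.49) and Phgdh of serine synthesis (+0.45), with adjusted p = 0.0443, 0.0387 and 0.0324. Each of the 3 lost its call whichever array was left out (adjusted p from 0.0509 to 0.164).

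Of 9 tested genes of G2 and mitosis, 6 rose, 0 fell and 3 were not called, and 9 were higher when adjusted over the list alone. The mitotic kinase Plk1 rose by 1.21 (SE 0.08, adjusted p = 0.00190), the cyclin Ccnb1 by 1.16 (SE 0.10, adjusted p = 0.00356), the spindle protein Nusap1 by 1.08 (SE 0.08, adjusted p = 0.00231) and Cdc20 by 1.04 (SE 0.10, adjusted p = 0.00408). The list had a camera adjusted p = 2.25e-08 (adjusted p = 0.304 with an estimated correlation). Of 13 genes of DNA replication, 5 rose, 0 fell and 8 were not called (10 higher when adjusted over the list alone; camera adjusted p = 1.52e-05; adjusted p = 0.313 with an estimated correlation). Rrm2 of ribonucleotide reductase rose by 1.03 (SE 0.10, adjusted p = 0.00477), Cdc6 by 0.88 (SE 0.17, adjusted p = 0.0345), E2f2 by 0.77 (SE 0.08, adjusted p = 0.00552) and Uhrf1 by 0.53 (SE 0.08, adjusted p = 0.0160). Dimmer probes of Cdc6 (+0.28), E2f2 (+0.12) and Uhrf1 (+0.08) were not called. Cdc6 lost its call without GFP-positive replicate 1 (adjusted p = 0.126) or 2 (adjusted p = 0.101), and Uhrf1 without GFP-positive replicate 1 (adjusted p = 0.0733) or GFP-negative replicate 1 (adjusted p = 0.0576) or 2 (adjusted p = 0.0728). Among 7 genes of cell cycle brakes and MYC, Cdkn1a rose, Btg1 fell and 5 were not called (2 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.704).

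Of 15 tested B-cell identity factors and receptors, 7 fell, 0 rose and 8 were not called, and 9 were lower and 1 higher when adjusted over the list alone. A positive sign was seen in 2 of the 15. Beside Cd72, Fcer2a and Bach2, the transcription factor Spib fell by 0.91 (SE 0.13, adjusted p = 0.0149), a call lost without GFP-positive replicate 1 (adjusted p = 0.0666) or 2 (adjusted p = 0.0575). Camera called the list (adjusted p = 1.52e-05; adjusted p = 0.304 with an estimated correlation). In the list of MHC class II presentation, 4 of 8 members fell, 0 rose and 4 were not called, with 4 lower when adjusted over the list alone. The 4 that were not called had a positive sign. H2-DMa, H2-DMb2 and H2-DMb1, chains of the peptide-loading chaperone, fell by 1.11 (SE 0.13, adjusted p = 0.00868), 0.92 (SE 0.08, adjusted p = 0.00373) and 0.87 (SE 0.08, adjusted p = 0.00423), and H2-Ab1, a class II chain, by 0.97 (SE 0.09, adjusted p = 0.00466). H2-Ab1 read 15.93 and 15.95 in GFP-negative cells, at the top of the scale, where the size of a difference is less certain, and its dimmer probe had a change of -1.12. The invariant chain Cd74, chosen after its value was seen, read 16.06 and 16.01 at the top of the scale. Camera called this list (adjusted p = 0.0438; adjusted p = 0.355 with an estimated correlation), but not without GFP-negative replicate 1 (adjusted p = 0.0525), with the mean of a gene's probes (adjusted p = 0.0520) or with cyclic loess (adjusted p = 0.0654).

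In the list of response to IL-4, CD40 and NF-kB, 1 of 9 members rose, 2 fell and 6 were not called (2 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.850). Il4i1 and Fcer2a fell as given above, and Socs2, a cytokine signalling inhibitor, rose by 1.07 (SE 0.19, adjusted p = 0.0266). Its call was lost without GFP-negative replicate 1 (adjusted p = 0.0625) or 2 (adjusted p = 0.0586). Of the BAFF and APRIL receptor list 2 members were tested, too few for camera. Cd40, the receptor of the stimulus in the culture, fell by 1.06 (SE 0.09, adjusted p = 0.00301; also lower when adjusted over the list alone), and Tnfrsf13b, the receptor TACI, had a change of -0.02 (SE 0.12, adjusted p = 0.952). Tnfrsf17, the receptor BCMA, was not analysed here.

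Regulators of apoptosis were the study's focus. Of 6 tested pro-survival BCL-2 members, 2 fell, 0 rose and 4 were not called, and 3 were lower when adjusted over the list alone. Bcl2a1b fell by 1.11 (SE 0.15, adjusted p = 0.0120) and Bcl2a1d by 1.09 (SE 0.18, adjusted p = 0.0219), while Bcl2a1a had a change of -0.65 (SE 0.17, adjusted p = 0.0752). The A1 genes are near-identical copies, and probes may not tell them apart. A set test of this list may therefore count the same transcript more than once. No member outside the A1 genes was called in the main fit. Bcl2 had a change of -0.33 (SE 0.12, adjusted p = 0.150), with +0.03 at its second probe, Bcl2l2 of -0.15 (adjusted p = 0.502) and Bcl2l1, detected on 2 arrays at the dim end, of -0.08 (adjusted p = 0.594). The list was called by camera (adjusted p = 0.00805; adjusted p = 0.355 with an estimated correlation), but fry, which tests the list's own direction, gave an adjusted p = 0.0602. The call of Bcl2a1d was lost without GFP-negative replicate 1 (adjusted p = 0.0540), and Bcl2a1a passed without GFP-negative replicate 2 (adjusted p = 0.0146). With the replicate number as a block, Bcl2a1a (adjusted p = 2.40e-04) and Bcl2 (adjusted p = 0.0206) also passed, both with a negative sign, so whether these genes fell depends on a pairing that the labels do not state. Mcl1 was not analysed here. Of the pro-apoptotic members, Pmaip1 (NOXA) had a change of +0.13 (SE 0.15, adjusted p = 0.673) and Bok, detected on 2 arrays, of +0.01 (SE 0.08, adjusted p = 0.961), with neither called when adjusted over the list alone. Among 11 genes of death receptors and caspases, 2 rose, 0 fell and 9 were not called (2 when adjusted over the list alone; camera adjusted p = 0.0936). This list passed with fry (adjusted p = 0.0180) and with camera when dim probes were not filtered (adjusted p = 0.0399). Birc5, or survivin, an inhibitor of apoptosis that also acts in mitosis, rose by 0.89 (SE 0.08, adjusted p = 0.00422).

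**Figure D3:**
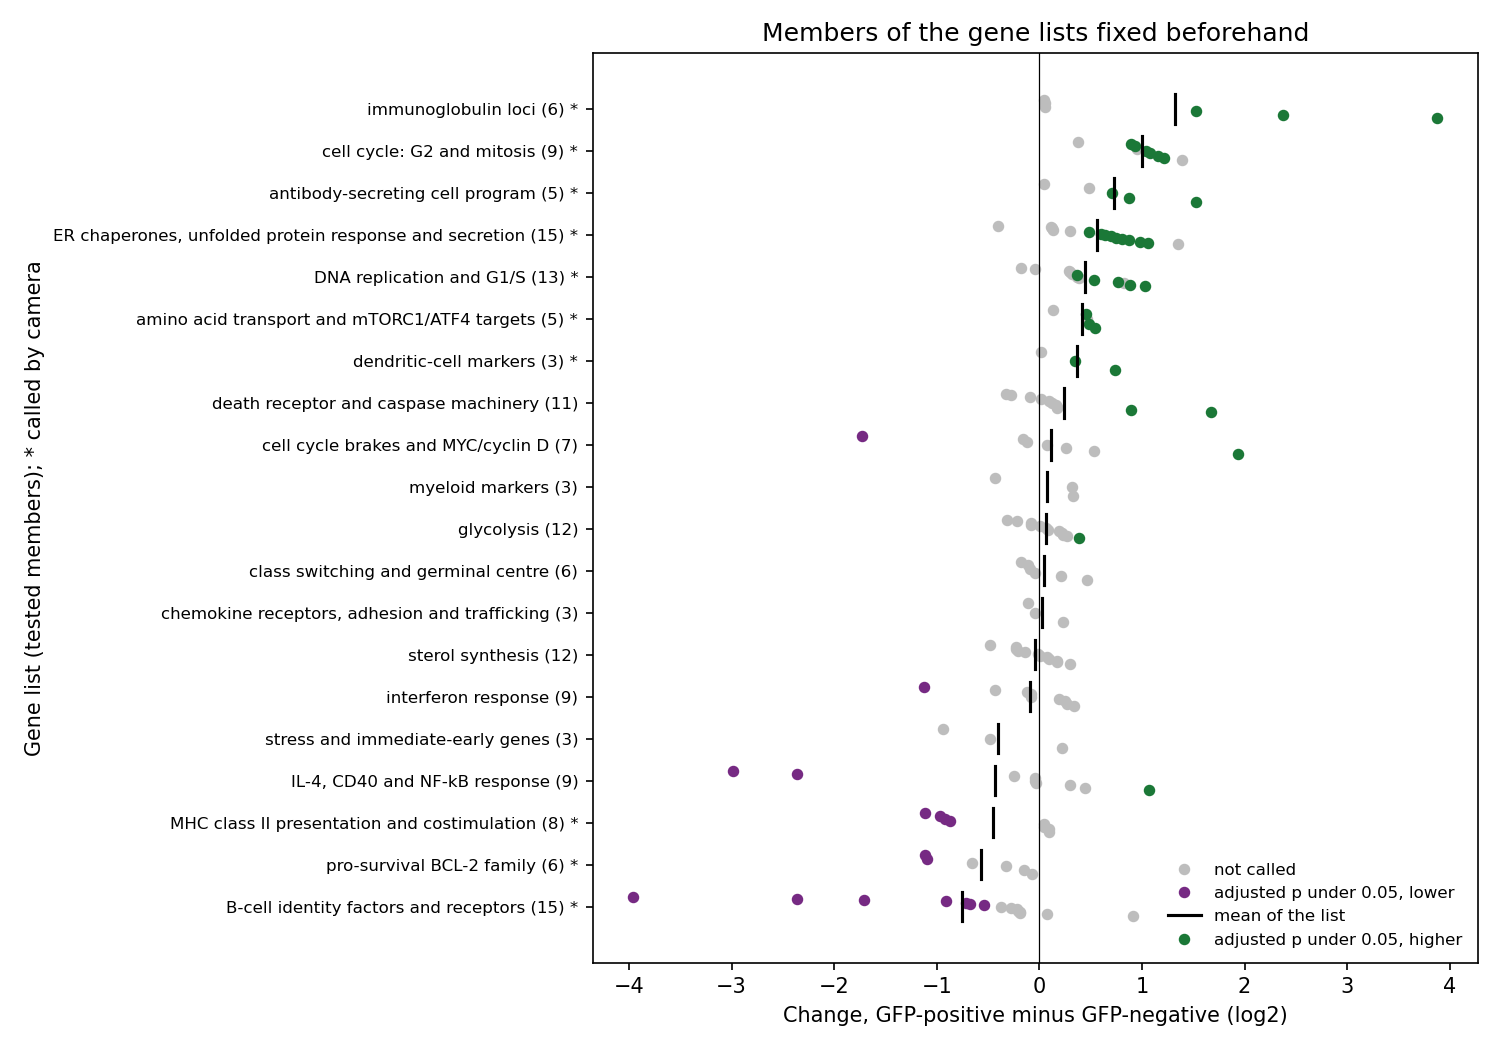
Change of each tested member (log2, GFP-positive minus GFP-negative, horizontal axis) for the 20 lists with at least 3 tested members, ordered by their mean. Green and purple points passed an adjusted p under 0.05 over all features, grey points did not, black ticks are list means, and asterisks mark lists called by camera. Mean changes ran from -0.76 for B-cell identity to +1.32 for immunoglobulin loci.

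For several lists a shift was not established, which with 2 against 2 arrays does not show that there was none. Camera did not call glycolysis (1 of 12 members higher, 0 lower, 0 when adjusted over the list alone; adjusted p = 0.383), where Pfkm rose by 0.38 (SE 0.08, adjusted p = 0.0431) and lost the call whichever array was left out (adjusted p from 0.0964 to 0.194). In the interferon response, 1 of 9 members fell, 0 rose and 8 were not called (1 higher and 1 lower when adjusted over the list alone). Oas1a, an antiviral enzyme, fell by 1.13 (SE 0.09, adjusted p = 0.00282), and the list's mean (-0.09) and camera's upward direction differ in sign (adjusted p = 0.997). No member was called, over all features or over the list alone, among 12 genes of sterol synthesis (camera adjusted p = 0.881), 6 of class switching and the germinal centre (0.881), 3 of chemokine receptors and adhesion (0.881) and 3 stress and immediate-early genes (0.881). The members with the smallest p were Insig1 (+0.30, adjusted p = 0.0705) for sterol synthesis, Plxnb2 (+0.46, adjusted p = 0.0900) for class switching and Egr2 (-0.94, adjusted p = 0.481) for stress genes. Plxnb2 passed without GFP-positive replicate 1 (adjusted p = 0.0440). With the replicate number as a block, Egr2 (adjusted p = 4.48e-07), Plxnb2 (adjusted p = 0.00286) and Insig1 (adjusted p = 0.0259) passed, so their calls depend on a pairing that the labels do not state.

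Markers of other cell types were mostly dim. Of 3 tested dendritic-cell markers, Batf3 rose by 0.74 (SE 0.08, adjusted p = 0.00566) and Tcf4 by 0.35 (SE 0.08, adjusted p = 0.0466), and 1 was not called (2 when adjusted over the list alone). Both are transcription factors that B-lineage cells can express too. Camera called the list (adjusted p = 0.0392; adjusted p = 0.347 with an estimated correlation), but not without GFP-negative replicate 1 (adjusted p = 0.0525), GFP-positive replicate 2 (adjusted p = 0.0882) or GFP-negative replicate 2 (adjusted p = 0.0718), with the replicate block (adjusted p = 0.0681) or with a trend in the variance prior (adjusted p = 0.0508), and Tcf4 lost its call whichever array was left out (adjusted p from 0.140 to 0.169). No myeloid marker was called among 3 tested over all features, and 2 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.442; fry adjusted p = 0.0180). Itgam, detected on 2 arrays, had a change of +0.32 (adjusted p = 0.0562) from a GFP-negative level at background. With each GFP-negative array set no lower than the dimmest probe detected on all 4 arrays, Itgam was higher by 0.10 on this scale. It passed with the replicate block (adjusted p = 0.0154). The T-cell list had 2 tested members, the erythroid list 2, the stromal list 1 and the NK-cell list 0, and 0 were called over all features or over the list alone. Values were +0.19 for Il7r (adjusted p = 0.227, at background in GFP-negative cells), -0.32 for Hbb-b1 (adjusted p = 0.439) and +0.04 for Pecam1 (adjusted p = 0.894). Hbb-b1 passed without GFP-negative replicate 2 (adjusted p = 0.0455) and with the replicate block (adjusted p = 0.0450).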

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

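The filters, the choice of probe, the variance prior, cyclic loess and centring kept all 4 main counts within 1.5 times. A stricter adjusted p and a block by replicate number moved the counts of higher and lower features further. With the block, the count of features changed at least 2-fold and that of called lists stayed within this range. At an adjusted p under 0.01, 360 features were higher and 215 lower. With the replicate number as a block (replicate block), 1861 were higher and 2125 lower, and all 1692 features called without it were among the 3986 called with it. With this block 7 named genes passed that had not passed without it, Bcl2a1a (adjusted p = 2.40e-04), Bcl2 (0.0206), Plxnb2 (0.00286), Insig1 (0.0259), Egr2 (4.48e-07), Itgam (0.0154) and Hbb-b1 (0.0450). Insig1 (0.0380 and 0.0473) and Itgam (0.0292 and 0.0377) also passed with no filter on dim probes and with a filter on mean intensity, and Itgam with a trend in the variance prior (0.00476). The labels give the groups the same replicate numbers but no shared origin, and with only 2 numbers the correlation of the deviations from the group means (0.44) does not settle a pairing. Without the receptor segment probes, an alternative chosen after seeing the data, 280 features in place of 430 changed at least 2-fold. Of the 430, 148 were such probes, and the refit accounts for the other difference. Cyclic loess turned the lean of the features outside these probes, from 708 higher and 804 lower to 801 and 626. With an estimated correlation 0 lists were called, in place of 10, in a test that has few degrees of freedom with 4 arrays; fry called 11. Leaving out 1 array, where the lone array is assumed to vary like the other group, gave 492 to 618 higher and 336 to 610 lower features, in part because fewer arrays were fitted. Of the 47 called named genes, 33 kept the call under every alternative, 14 lost it without some array and 8 under a setting with all arrays (Ell2, Cdc6 and Tars with another filter, Tcf4 with another filter or a trend, Pfkm, Sars and Phgdh with a trend, and Uhrf1 with the mean of its probes, at an adjusted p of 0.0797), and 0 changed direction. Of the 10 called lists, 7 kept the call under every setting but the estimated correlation, and the pro-survival BCL-2, MHC class II and dendritic-cell lists did not.

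Values that turned direction were all uncalled and close to 0 or variable, and the cause was not tested. The called named genes had no overlap between the groups, so leaving out 1 array could not turn their direction. With cyclic loess the mean of the sterol list was 0.023 and the change of Tnfrsf13b 0.0071. Over the fits without 1 array, list means ran from -0.032 to 0.12 for class switching, from -0.063 to 0.11 for chemokine receptors and from -1.15 to 0.35 for stress genes. Changes ran from -0.30 to 0.0017 for Bcl2l2, from -0.032 to 0.053 for Bok, from -0.031 to 0.28 for Pmaip1, from -0.66 to 0.018 for Hbb-b1, from -0.12 to 0.19 for Pecam1 and from -0.16 to 0.13 for Tnfrsf13b. Settings fixed beforehand that need the unnormalized signals were not run. They were the raw signal without background correction, normexp with an offset of 50, and median scaling or cyclic loess after the neqc background step. The use of the authors' normalized values, fixed as an alternative, became the main setting. The effect of background correction on dim genes is therefore unknown.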

Other observations

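The family groups and the tests of the top of the scale and of the sort, with its limit on features near background, were chosen after the results were seen; the p53 test was written before the values of the genes it uses were looked at. Beyond the fixed lists, genes were grouped into 10 families by symbol. Among 24 genes grouped by symbol as vesicle coats and transport, 5 rose and 0 fell. They included the cargo receptors Tmed2 (+0.67, adjusted p = 0.0154) and Tmed10 (+0.65, adjusted p = 0.0120) and the coat protein Sec24a (+0.57, adjusted p = 0.0116). The translocon subunit Sec61b and Sec63 entered by their symbols and are also in the secretion list, so this group is not made up of vesicle proteins alone. Camera called the group (adjusted p = 0.0476), and not with an estimated correlation (adjusted p = 0.282). Calls were lost for Tmed2 without GFP-positive replicate 1 (adjusted p = 0.0715) or 2 (adjusted p = 0.0528), and for Tmed10 and Sec24a without GFP-positive replicate 1 (adjusted p = 0.0577 and 0.0575) or GFP-negative replicate 2 (adjusted p = 0.0563 and 0.0538). Sec63 lost its call without GFP-negative replicate 1 (adjusted p = 0.0514) or 2 (adjusted p = 0.0714) or GFP-positive replicate 2 (adjusted p = 0.0622). All 10 tubulins had a positive change (median +0.42), but only Tubb2b was called (+0.42, adjusted p = 0.0468, and 0.0868 or more whichever array was left out; camera adjusted p = 0.00158; adjusted p = 0.282 with an estimated correlation). Of 4 immunity GTPases, Gimap7 (+0.81, adjusted p = 0.0192) and Gimap5 (+0.56, adjusted p = 0.0214) rose (camera adjusted p = 0.0346; adjusted p = 0.282 with an estimated correlation). Gimap7 lost its call without GFP-positive replicate 1 (adjusted p = 0.0763) or 2 (adjusted p = 0.0721), and Gimap5 without GFP-negative replicate 1 (adjusted p = 0.0634) or 2 (adjusted p = 0.0864) or GFP-positive replicate 2 (adjusted p = 0.0744). Of 72 ribosomal protein genes and kinases with such symbols 2 rose and 4 fell, and of 17 proteasome subunits 0 were called.

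Single genes with large changes, chosen after their values were seen, included the survival kinase Pim2 (+1.52, adjusted p = 0.00113), the interferon-induced Ifitm1 (+1.47, adjusted p = 0.00122), Hsd11b1 (+1.40, adjusted p = 0.00439), which activates glucocorticoids, and the adhesion molecule Alcam (+1.21, adjusted p = 0.00260). The transcription factor Foxp1 fell by 1.22 (adjusted p = 0.00183) and the interferon-gamma receptor chain Ifngr2 by 1.01 (adjusted p = 0.0103). Among 13 mitochondrial transcript probes 1 was called, the files' own ND5 probe, at -1.01 (adjusted p = 0.00863). A dim probe assigned to ND5 by its number had a change of +0.27 (adjusted p = 0.106), so the probes differ in sign. The immediate-early gene Egr2 split by replicate number within both groups, with 10.58 and 9.02 in GFP-positive replicates 1 and 2, and 11.62 and 9.87 in GFP-negative replicates 1 and 2.

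Ighm, Igkc and the bright Iglv1 probe were not called and had changes of 0.04 to 0.06, while dimmer immunoglobulin probes rose. Signal near the top of the scale that cannot show a change is a candidate explanation. The 106 brightest features had a 90th percentile of absolute change of 0.24, against 1.34 for means between 13 and 14. In genes with a probe at the top and another at 15 or less, the dimmer probe moved more in 100% of the 3 genes (Iglv1, Rpl23 and Rpl27a; exact 95% interval from 29.2% to 100%), too few to decide. The dimmer Rpl23 probe read 8.38, at the dim end, and the bright and dim Rpl27a probes moved in opposite directions (+0.12 and -0.39). A true lack of change in genes already near their highest level cannot be told apart from a limit of the scale.

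The eGFP probe read 9.34 in GFP-negative cells, above the undetected probes. GFP-positive cells in the GFP-negative sort could give such a signal, but would also bring every other transcript in the same proportion. After subtraction of the median of undetected probes, eGFP in GFP-negative cells stood at 5.47% and 6.36% of its GFP-positive level in replicates 1 and 2. Among detected features with a GFP-positive mean of 10 or more, 3 lay below it in both numbers. The rule written for this test took 3 or more as speaking against GFP-positive cells in that sort. Only 2 of them were above the band of undetected probes in GFP-negative cells, and with this limit the rule was not met. In replicates 1 and 2 these stood at 5.04% and 4.12%, and at 2.13% and 1.97%. The percentages read a scale whose dim end has no known linear equivalent. Such cells are therefore neither shown nor excluded, and cannot be told apart from GFP transcription below the gate.

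Cdkn1a rose, as did Ccng1 (+1.27, adjusted p = 0.00549) and Sfn (+1.21, adjusted p = 0.00507), all 3 known p53 targets, while Apaf1 (+0.02, adjusted p = 0.953), Pmaip1 (+0.13, adjusted p = 0.673) and Tnfrsf1a (+0.17, adjusted p = 0.278), also targets and seen before, were not called. A p53 response in GFP-positive cells is a hypothesis from the 3 that rose. Of 36 targets listed before the test, 3 were tested and had not been seen: Zmat3 rose by 0.95 (adjusted p = 0.0197, lost without GFP-negative replicate 1 at 0.0505), Xpc fell by 0.52 (adjusted p = 0.0192, lost without GFP-positive replicate 1 at 0.0835 and GFP-negative replicates 1 and 2 at 0.0679 and 0.0790) and Aen had a change of +0.15 (adjusted p = 0.338). Their camera p was 0.54, with a mean change of 0.19 (SE over genes 0.43), and 3 genes that go both ways leave the hypothesis undecided.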
